A study of Mus musculus with 3 samples.

How the data were processed

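The data were 3 NimbleGen mouse whole-genome copy number arrays with 2 colours, each comparing DNA of Lin-Sca+ bone marrow cells of G-CSF and diluent treated C57BL/6 mice. Per the labels, test and reference DNA were labelled with Cy3 and Cy5 by random priming, and copy number was analysed with NimbleScan and BioDiscovery Nexus, whose versions are not given in the sources used here. Per the file headers, each array has a log2 signal for each channel and a log2 ratio at 3 stages, which are raw, spatially corrected, and corrected and normalized. The methods of the spatial correction and normalization are not given in the sources used here. In the deposited values each ratio equals Cy3 (532 nm) minus Cy5 (635 nm) on the log2 scale, within 0.001. The GC content of each probe is a fraction per the file headers, and was used in percent. The column and row of each probe on the array surface, other numbers that are positions and not measurements, were also taken as deposited. The value table of the series equalled the corrected ratio exactly, so using it as an alternative moved nothing. In the normalized values the median log2 signals of the channels differed by at most 0.001 on each array, so a difference in total DNA between the channels is not read here.

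The source name and treatment protocol put diluent in Cy3, while the characteristics put G-CSF in Cy3. The titles name G-CSF but no channel. The file headers call the 532 nm channel EXP and the 635 nm channel REF, names that do not say which treatment each held. No direction relative to treatment was therefore assigned. No array was turned, since the labels give the same dyes for each array. The positive correlation between arrays does not show that the treatments lay in the same channels, because a signal tied to the dyes would correlate too.

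None of the 21 chromosome lengths given in the files equals that of the reference genome used here, GRCm38, although the labels name that assembly for later look-ups. Coordinates are those of the files and were not converted. Gene names need an annotation of the same assembly, so the tests of genes, antigen receptor loci and gene lists that had been fixed beforehand were not run, and no gene is named. The deposited files were read as per-probe values without segment calls, so the authors' segments are not analysed here, and the overlap of segments between arrays, planned for them, was computed on the segments found here.

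The corrected log2 ratio was the main value. It was chosen over the raw ratio once the columns were known and before any result was computed. Each array was centred on the median of its autosomal probes, with no loess or quantile step added to the authors' normalization. Probes were averaged in 100 kb bins, and the 25806 of 26244 bins with 10 or more probes were kept (median 28 probes). Bins and chromosome means were tested against 0 over the 3 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only), with Benjamini-Hochberg adjustment and a threshold of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Random steps had a fixed seed.

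Each array was segmented by recursive circular binary segmentation on means of 10 neighbouring probes. A split was kept where its statistic exceeded the 99.9th percentile of the maximum over 1000 shuffles of the chromosome. Shuffling removes the correlation of neighbours, so the threshold is lenient where the profile is wavy. Segments with 5 or more means and an absolute mean of at least 0.2 were counted. Segments of different arrays were recurrent where they overlapped by 50% or more of both lengths with the same sign, compared with 1000 circular shifts along the genome.

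The alternatives fixed before the data were examined were leaving out each array, no centring, the value table of the series, other bin widths, probe minimums, bin medians, dim probes left out, an unmoderated statistic, other sizes and overlaps, and removal of a running median over 5 Mb, the planned substitute for a GC correction without a genome of the same assembly. Chosen after seeing the data were the raw and spatially corrected ratios, a GC regression, and a search for shifts of a lone array. The GC regression was a least-squares fit, on autosomes, on probe GC and mean probe GC within 100 kb and 1 Mb, with square terms. It removes any true signal that follows GC too. For the search, each array was regressed on the other 2 arrays, their running means over 101 probes and GC, and the residual was segmented on means of 5 probes, with a minimum of 10 probes. A version with a fixed threshold of 6 was looked at before the shuffled threshold was used. The minimum of 10 probes was set after the region on chromosome 1 had been seen.

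The text names bins and segments by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest bin means past the threshold, the 5 segments with the largest absolute mean and the 5 longest in each array, and the 10 recurrent segments with the largest absolute mean. The region on chromosome 1 and the segments found after GC regression are outside that rule and were chosen after their values were seen.

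The steps were tested on simulated data. For bins shifted in all arrays, 25806 bins were simulated. Of those shifted by 0.1, 44% were recovered, and of those shifted by 0.2, 100%, and 13 unchanged bins were called. The simulated errors were independent between arrays, whereas the real ratios of single probes correlated between arrays at a mean r of 0.716. The 13 calls therefore give no bound on false calls among the real bins. For the segmentation, in shuffled chromosome 1 probes of each array, 36.7% of planted segments of 60 probes shifted by 0.2 were recovered, 96.7% of those shifted by 0.4, and 100% of segments of 200 probes at either size. For the search for shifts of a lone array, 20% of planted segments of 40 probes shifted by 0.2 and 100% of those shifted by 0.4 were recovered, but only 33.3% of segments of 20 probes shifted by 0.4. Recovery of planted segments did not apply the rules of length and absolute mean by which segments were counted. A planted shift of 0.2 lies at the minimum absolute mean of 0.2. At that shift the shares therefore show detection only, and not how many such segments would be counted. Small or weak shifts can be missed.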

Results

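Genomic DNA of Lin-Sca+ bone marrow cells, a preparation depleted of cells with mature lineage markers and enriched for haematopoietic stem and progenitor cells, was compared by array comparative genomic hybridisation. The mice were of strain C57BL/6 and had received G-CSF, the growth factor that drives neutrophil production and mobilises stem cells, or its diluent for 4 months. The series addresses DNA damage after G-CSF, and the arrays address whether DNA copy number differed between the treatments. There were 3 arrays in 1 group, each hybridised with G-CSF and diluent DNA in the Cy3 and Cy5 channels, and they are called arrays 1, 2 and 3 after the mouse number in the labels. Each array held 713358 probes with a median spacing of 3537 bp. The labels contradict each other on which channel held the G-CSF DNA, so a positive value below means more Cy3 than Cy5 signal, and no value is given as a gain or a loss under G-CSF. The labels give the dyes alike for all 3 arrays, and every ratio is read as Cy3 over Cy5; that the treatments lay in the same channels on each array was not tested. The labels do not say whether the diluent DNA was shared between arrays, so p-values measure only the spread between these 3 hybridisations. That spread is pooled by limma over bins or over sequences.

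The spread between neighbouring probes differed between the arrays and was lowest in array 3. It is not noise alone, since the ratios of single autosomal probes correlated between arrays, with Pearson's r from 0.68 to 0.741. The SD of the log2 ratio estimated from differences between neighbouring probes was 0.28 in array 1, 0.27 in array 2 and 0.21 in array 3. The correlation of a probe with its next neighbour was 0.133, 0.131 and 0.0788 in the same order. The number of arrays limits the precision of every mean below.

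The arrays shared a common profile along the autosomes. Over 23980 autosomal bins of 100 kb, Pearson's r was 0.934 between arrays 1 and 2, 0.88 between arrays 1 and 3 and 0.862 between arrays 2 and 3, and Spearman's rho was 0.923, 0.87 and 0.852. These correlations are across bins, which are not independent replicates, and no p-value is given. Of 25806 bins on all chromosomes, 20397 (79.0%) had the same sign in all 3 arrays, against 25% by chance for independent arrays. After a regression of the ratios on GC content, chosen after seeing the data, r was 0.803, 0.717 and 0.674.

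The profile followed GC content in every array. Bins with the highest GC had a higher Cy3/Cy5 ratio, and bins with the lowest GC a lower one. In the 1217 bins of highest GC, mean probe GC 45.6%, the mean log2 ratio was 0.22, 0.21 and 0.11 in arrays 1, 2 and 3. In the 1210 bins of lowest GC, mean probe GC 41.1%, it was -0.11, -0.11 and -0.072. The correlation of bin mean and GC across bins was 0.748, 0.757 and 0.677. A rise of GC by 10 percentage points went with a log2 ratio higher by 0.79, 0.76 and 0.43 between bins, and by 0.21, 0.22 and 0.15 between probes of the same bin. Over the 19 autosomes, the mean ratio and mean probe GC had a Pearson's r of 0.953 and a Spearman's rho of 0.958, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. Without the 2 autosomes farthest from the median GC, r was 0.918. This was the only relation across chromosomes that was computed, and autosomes of the same arrays are not independent samples.

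**Figure D1:**
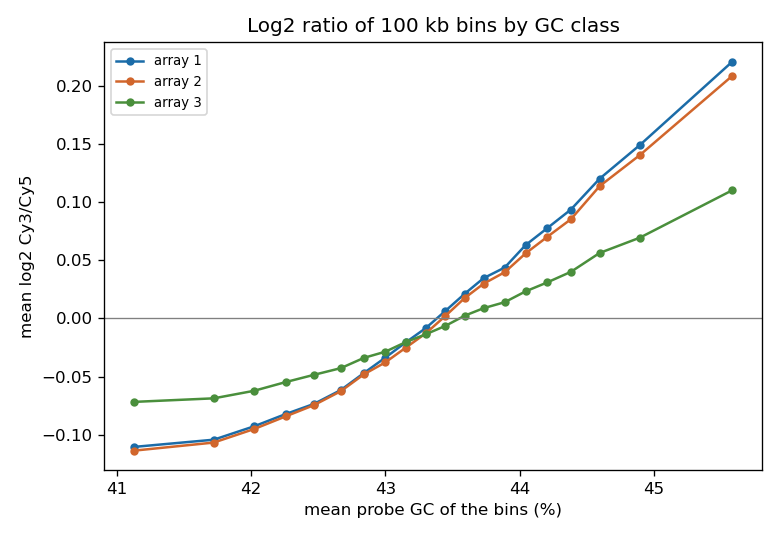
Mean log2 Cy3/Cy5 ratio (vertical axis) of autosomal 100 kb bins in classes of mean probe GC in percent (horizontal axis), with a line for each of the 3 arrays and a point for each class. The ratio is higher in classes of higher GC in every array, and array 3 spans the smallest range.

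Whole chromosomes differed little from the autosomal median, with the X chromosome the farthest below it. The mean log2 ratio of the X chromosome was -0.074 ± 0.025 (SD, n = 3), with -0.092, -0.085 and -0.046 in arrays 1, 2 and 3 (limma adjusted p = 4.8e-04). Of its 1567 bins, 1078 (68.8%) were past the threshold with a negative and 87 (5.55%) with a positive mean. After GC regression these shares were 24.9% and 12%, and the negative share of single autosomes was then between 18.0% and 26.6%. The positive share of single autosomes was then between 14.2% and 28.4%, so that of the X chromosome lay below all of them. Chromosome 11 was highest among the autosomes at 0.041 ± 0.018 (SD, n = 3; limma adjusted p = 0.00197), and chromosome 3 lowest at -0.031 ± 0.0032 (SD, n = 3; limma adjusted p = 0.00149). Unplaced Y sequence was at 0.039 ± 0.012 (SD, n = 3; limma adjusted p = 0.00149). Chromosome Y was at -0.031 ± 0.029 (SD, n = 3; limma adjusted p = 0.0228), with array 3 at 0.0018, on the other side of 0. Chromosomes 5, 7, 17 and 19 also passed with positive means and chromosomes 1 and 16 with negative means, for 11 of 22 sequences in all, each with a mean below 0.05 in size for the autosomes. The exact two-sided sign-flip permutation test of 3 arrays cannot give a p below 0.25. After GC regression 5 sequences passed. They were unplaced Y sequence at 0.066 (limma adjusted p = 2.89e-21), chromosome Y, whose sign turned, at 0.047 (limma adjusted p = 4.98e-16), the X chromosome at -0.01 (limma adjusted p = 0.0348), chromosome 10, which had not passed before, at -0.01 (limma adjusted p = 0.0352), and chromosome 7 at 0.0096 (limma adjusted p = 0.04). Chromosomes 11 and 3 were then at 0.0057 and -0.0066 and did not pass (limma adjusted p = 0.222 and 0.166). Unplaced Y sequence was at 0.084, 0.061 and 0.053 in arrays 1, 2 and 3 after GC regression. The variance in limma is pooled over the 22 sequences, which were measured on the same 3 arrays and are not independent. Its smallest p-values here are therefore far smaller than 3 arrays alone would give. With the authors' raw ratio, chromosomes 11, 7 and 17 passed, with chromosome 11 at 0.049 (limma adjusted p = 0.00308) and chromosomes 7 and 17 at 0.035 and 0.034 (limma adjusted p = 0.0458 for each). With that ratio the X chromosome was at -0.029, chromosome 3 at -0.014 and unplaced Y sequence at 0.0075, and none of these passed (limma adjusted p = 0.084, 0.414 and 0.82). With their spatially corrected ratio the X chromosome was at -0.043 (limma adjusted p = 0.0164) and unplaced Y sequence at -0.0084 (limma adjusted p = 0.429). Without array 1 only 4 sequences passed, and without array 2 only 3.

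**Figure D2:**
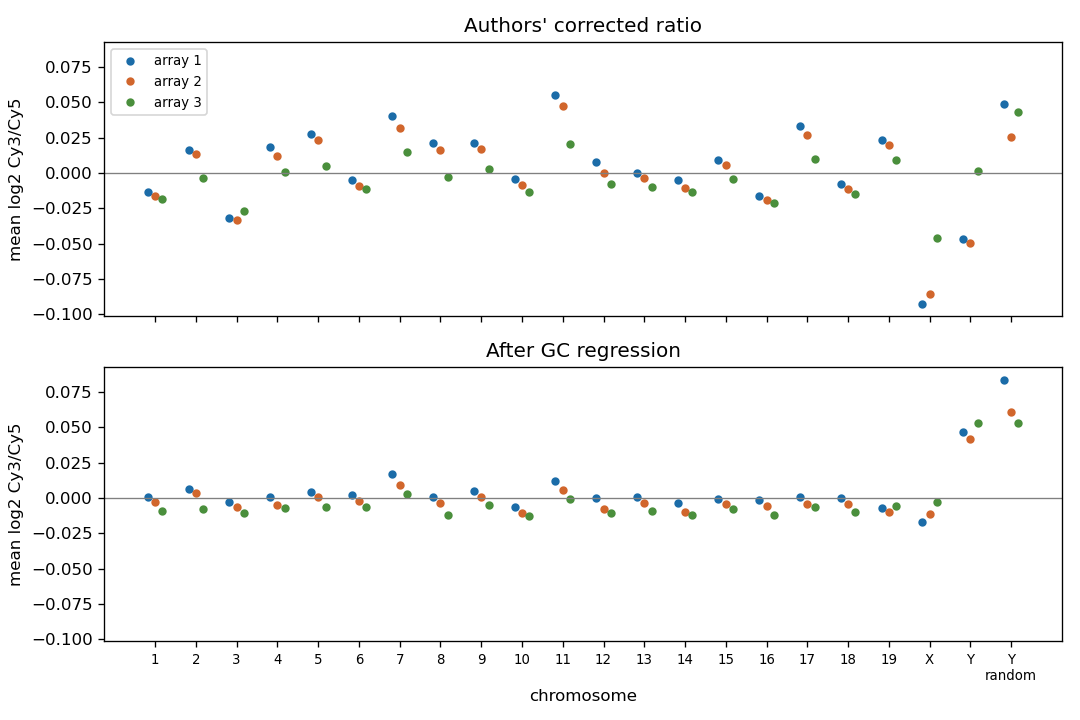
Mean log2 Cy3/Cy5 ratio (vertical axis) of each chromosome (horizontal axis), with a point for each of the 3 arrays, before (top) and after (bottom) regression on GC content. The X chromosome lies at -0.092, -0.085 and -0.046 before the regression and at -0.017, -0.012 and -0.0028 after it, and chromosome Y turns from negative in arrays 1 and 2 to positive.

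At 100 kb, bin means away from 0 in common to the arrays were widespread and mostly small. They are not regional shifts alone, since probes of the same bin also shared deviations between arrays, with a covariance of 0.039 to 0.057. Averaging over the probes of a bin shrinks these deviations but does not remove them. They can put a bin mean away from 0 in all arrays without a regional shift. Of 25806 bins, 15880 passed limma's adjusted p under 0.05, 6903 with a positive and 8977 with a negative mean, and 7643 of them had a mean of at least 0.1 in size (3845 positive, 3798 negative). With the authors' raw ratio the balance turned, with 5851 positive and 4546 negative bins among 10397, and 4030 positive and 2053 negative bins of at least 0.1 in size. In that ratio every autosome mean of array 1 was positive, from 0.00097 on chromosome 3 to 0.077 on chromosome 11, unlike in arrays 2 and 3. Whether this offset of array 1 turned the balance was not tested. The highest bin lay on chromosome 6 from 114500001 to 114600000, with a mean log2 ratio of 0.57 ± 0.16 (SD, n = 3), mean probe GC 49.3% and 13 probes (limma adjusted p = 3.29e-05). The other 9 highest bins began on chromosome 8 at 125000001, 73200001 and 122800001, on chromosome 17 at 56500001, 6400001, 6700001 and 6800001, on chromosome X at 166600001 and on chromosome 5 at 30600001, with means down to 0.37. The lowest bin lay on chromosome 1 from 150500001 to 150600000, at -0.28 ± 0.03 (SD, n = 3), mean probe GC 41.9% and 29 probes (limma adjusted p = 3.29e-05). The other 9 lowest bins began on chromosome X at 134800001, 128600001, 126700001 and 61700001, on chromosome 1 at 22400001, on unplaced Y sequence at 18800001, on chromosome 14 at 95900001, on chromosome 4 at 29900001 and on chromosome 3 at 11500001, with means up to -0.22. After GC regression 10525 bins passed, 1718 of them with a mean of at least 0.1 in size, and 6472 bins passed with the same sign in both versions while 600 passed with opposite signs. The bin on chromosome 6 was then at 0.10, and those on chromosome 17 at 6700001 and 6800001 no longer passed (0.015 and 0.023, limma adjusted p = 0.532 and 0.395). Without array 1, 10276 bins passed. No bin passed the Benjamini-Hochberg adjustment of an unmoderated statistic, which gave 10799 bins at an unadjusted p under 0.05.

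Segmentation of each array found GC-rich regions with positive ratios in arrays 1 and 2 and none of that size in array 3. Segments of at least 50 probes and a mean of at least 0.2 in size numbered 23 in array 1, covering 79.7 Mb, 19 in array 2, covering 59.6 Mb, and 0 in array 3. At this size all 42 segments were positive, and their mean probe GC lay between 44.4% and 46.2%. At a mean of at least 0.1 in size, 23 of 106 segments of array 1 and 27 of 105 of array 2 were negative, with mean probe GC down to 41.7%, and with a 5 Mb running median removed 2 of 16 were negative at 0.2 or more in each of these arrays. The segment with the largest mean lay on chromosome 17 from 6228664 to 6941017 (190 probes), at 0.46 ± 0.023 (SE over probes) in array 1 and 0.44 ± 0.022 in array 2, where array 3 had a mean of 0.15. On chromosome 10 from 79037566 to 81113093 (590 probes) the means were 0.34, 0.33 and 0.16 in arrays 1, 2 and 3. In array 1 the next largest means were on chromosome 5 from 139712234 to 141260731 (0.30), on chromosome 17 from 56087490 to 57491443 (0.29) and on chromosome 8 from 121853012 to 128405646 (0.26). In array 2 they were on chromosome 8 from 121926942 to 125212562 (0.29), on chromosome 5 from 139712234 to 141440500 (0.28) and on chromosome 12 from 113341401 to 114505486 (0.27). The longest segments of array 1 were on chromosome 2 from 24832723 to 33776017 (0.24), chromosome 11 from 112614600 to 121069025 (0.24), chromosome 4 from 147251216 to 155630043 (0.21), the segment on chromosome 8 already named, and chromosome 17 from 23701357 to 30119468 (0.23). Those of array 2 were on chromosome 2 from 24867448 to 33702978 (0.22), chromosome 11 from 112614600 to 121032805 (0.22), chromosome 4 from 147251216 to 155630043 (0.20) and from 136201530 to 141740712 (0.24), and chromosome 2 from 164579515 to 168756643 (0.23).

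Of the 42 segments, 30 overlapped a segment of the other array by 50% or more of both lengths with the same sign. In 1000 random circular shifts the median was 0 and the highest number was 12 (one-sided permutation p = 0.001, the smallest these shifts can give). Bin means of arrays 1 and 2 correlated at 0.934, and a shared profile alone brings their segments together more often than random placement. The p-value therefore cannot tell recurrent copy number changes from that shared profile. The 10 recurrent segments with the largest means lay in the regions of chromosomes 17, 10, 5, 8 and 12 given above and on chromosome 7 from 19604907 to 20518946 (0.27 in array 2). The overlap rests on arrays 1 and 2. Without either of them the number was bound to be 0, since array 3 had no segment of that size. In the 30 recurrent segments array 3 had mean log2 ratios of 0.084 to 0.16. After GC regression none of the 42 segments was found again (0 overlapped a segment by 1 base or more). The segmentation then found 6, 5 and 0 other segments in arrays 1, 2 and 3, of which 8 were negative and 8 were recurrent.

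A region of array 3 alone stood apart from the shared profile, and was found by a search chosen after seeing the data. On chromosome 1 from 117106081 to 117260298 (154 kb, 45 probes, mean probe GC 41.9%) the mean log2 ratio was 0.32 in array 3, against -0.11 in array 1 and -0.097 in array 2. Against the 275 probes within 500 kb on either side, array 3 was higher by 0.39 ± 0.037 (SE over probes), array 1 by 0.0046 ± 0.043 and array 2 by 0.014 ± 0.046. In array 3, 43 of the 45 probes lay above the median of the flanks. With the mean of arrays 1 and 2 subtracted, the normalized log2 signal of array 3 in the segment was above the flanks by 0.38 ± 0.032 in Cy3 and by 0.0041 ± 0.025 in Cy5. The region had too few probes for the 50-probe rule of the segmentation fixed before the data were examined, and it has no replicate. Its probes were picked for their shift, so the SE understates the uncertainty and no p-value is given.

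**Figure D3:**
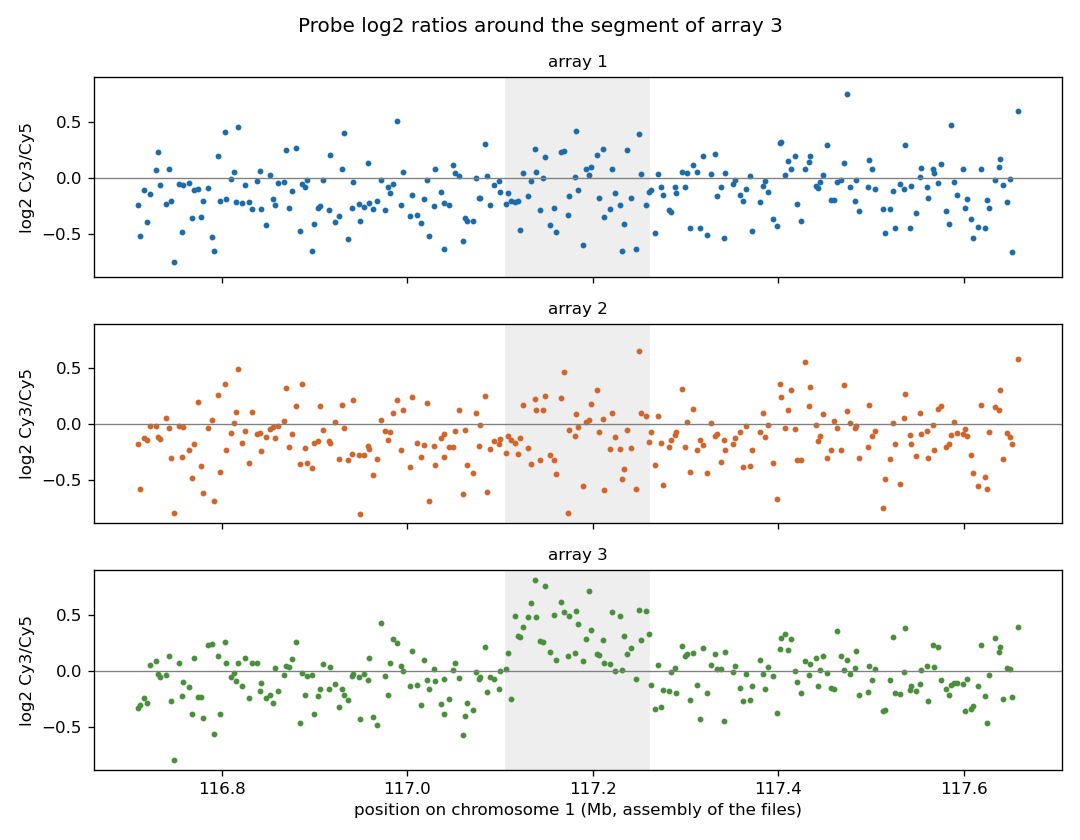
Log2 Cy3/Cy5 ratio of each probe (vertical axis) by position on chromosome 1 in Mb (horizontal axis), 1 panel for each of the 3 arrays, with the segment shaded. The shaded probes have a mean of 0.32 in array 3, and of -0.11 and -0.097 in arrays 1 and 2.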

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

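The GC regression, the raw and spatially corrected ratios, the search for shifts of a lone array and the 50-probe rule with 20 probes per mean were chosen after seeing the data. The cause was not tested where none is given. Without 1 array, 10276 to 18277 bins passed, 3 to 16 chromosome means and 0 to 30 recurrent segments. Bins past the threshold numbered 10525 after GC regression, 10397 with the raw ratio (5851 positive and 4546 negative, against 6903 and 8977) and 0 with the unmoderated statistic. At other bin widths, where the number of bins differs, they were 27985 of 50959 at 50 kb and 3797 of 5265 at 500 kb. Of at least 0.1 in size were 0 (unmoderated statistic), 3113 (running median removed), 1718 (GC regression), 17650 and 1169 (50 and 500 kb), and 933 at 0.2 or more, a number that was 574 without array 1, 1718 without array 3 and 38 after GC regression. With the raw ratio 4030 were positive and 2053 negative, against 3845 and 3798. Chromosome means passed in 18 cases without centring, 5 after GC regression, 3 with the raw ratio, and 0 with a running median removed, which takes out chromosome means by construction. Of named chromosomes, the sign turned with the running median for chromosome 1 (0.00048), 3 (0.00035), 11 (-0.0026) and unplaced Y sequence (-0.0079), with GC regression for 5 (-0.00057), 17 (-0.0033), 19 (-0.0075) and Y (0.047), and with the spatially corrected ratio for unplaced Y sequence (-0.0084). Segments in arrays 1, 2 and 3 numbered 15, 12 and 0 with 20 probes per mean (1 in array 3 with the 50-probe rule), 106, 105 and 20 at 0.1 or more (23, 27 and 0 of them negative), and 6, 5 and 0 after GC regression. In the residuals they numbered 0, 0 and 1 with 10 or more probes, 0, 0 and 0 with 50 or more, and 2, 0 and 1 with the fixed threshold. Recurrent segments numbered 184 at 0.1 or more and 8 after GC regression. The mean correlation of arrays was 0.716 for single probes, 0.965 at 1 Mb, 0.803 with the running median removed, 0.731 after GC regression and 0.797 with the raw ratio. Of the 20 named bins, 18 stayed past the threshold after GC regression with the same sign. Named chromosomes and bins kept their sign but fell short of the threshold in 39 further combinations of result and setting, most of them chromosome means without array 1 or 2, with the running median, or with the raw ratio, and kept sign and threshold in 71.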

Other observations

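Of the tests in this part, those of GC content, of copy number at single probes and of cycling cells were chosen after the result they measure had been seen, and the GC regression and the search for shifts of a lone array were added after seeing the data.

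After GC regression, 11 segments were found in arrays 1 and 2, none of them overlapping the 42 found before it. Of these, 8 were negative, in GC-rich regions where the ratio before regression was lower than the fit on GC predicted. On chromosome 14 from 3004892 to 4003301 the residual was -0.32 in array 1 and -0.36 in array 2, where the ratio before regression was 0.16 and 0.095. On chromosome 4 it was -0.30 in array 1 (from 41725582 to 42622419) and -0.29 in array 2 (to 42686186). Within the array 1 segment the ratio before regression was 0.036, 0.021 and 0.13 in arrays 1, 2 and 3. The median log2 intensity of the probes, over both channels, was above the autosomal median by 1.02 on chromosome 14 and 1.01 on chromosome 4. It was above it by 1.28 in the other negative segment of chromosome 14 in array 1 (from 6715905 to 7327399), and by 0.56 on chromosome X in array 2 (from 26660392 to 30572751). Probes that match many copies could be bright in both channels, but the remaining negative segment of array 1, on chromosome 17 from 84691498 to 85006824, exceeded the autosomal median by only 0.11, so this explanation stays open for the set.

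The regional profile shared by the arrays may come from a GC-dependent signal. The GC regression removed at least 84.3% of the regional covariance between arrays in every pair. Regional covariance is that of bin means, less the part expected from probe differences within bins that the arrays have in common. Bin means of the arrays still correlated at 0.674 to 0.803 after the regression, but bin means also hold the shared probe differences within bins. With that part taken out, the regional covariance was 0.00073 to 0.00157 after the regression, against 0.0053 to 0.01 before it. Copy number does not account for the part of the profile shared by single probes, since neighbouring probes share copy number and at most 15% of the shared covariance of probes lay between bins. A different share of cycling cells in the G-CSF and diluent preparations would act on regions, as would a labelling bias by fragment GC, and the slope on GC between bins was at least 2.87 times that within bins, so they cannot be told apart from these values. An effect of G-CSF, or of a shared reference DNA, also stays open and was not tested.

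The segment of array 3 on chromosome 1 from 117106081 to 117260298 had a residual of 0.38. It was the only one found in the residuals at a mean of at least 0.2 and 10 or more probes with the shuffled threshold. At that size no segment passed with 50 or more probes. At 0.1 or more, array 3 also had a segment of 325 probes on chromosome 4 from 41706360 to 43166570, with a residual of 0.11. The ratio there was 0.062, 0.046 and 0.13 in arrays 1, 2 and 3. Array 1 had the chromosome 1 region at 0.1 or more in size as well, with a residual of -0.16. That residual is taken against arrays 2 and 3, so the high ratio of array 3 lowers it. The ratio of array 1 itself was above the flanks by only 0.0046 ± 0.043 (SE over probes), so no separate shift of array 1 is read here. With the fixed threshold looked at earlier, array 1 had 2 further segments, on chromosome 18 from 80817270 to 80901136 (25 probes, residual 0.23) and on chromosome X from 166525781 to 166628877 (15 probes, residual 0.31). Tests written beforehand used array 3 with the mean of arrays 1 and 2 subtracted. They argue against a surface defect, since the nearest probes on the array were shifted by a median of 0.001. They also argue against the authors' correction, since the raw shift was 1.04 times the corrected shift. A few outlying probes are argued against too, since the median shift was 1.13 times the mean shift. In array 3 without the subtraction, the median shift was 0.357 and the mean shift 0.386. A difference in copy number of the Cy3 DNA of array 3 is a hypothesis that stays open, and whether it was inherited, arose in the marrow, or relates to G-CSF was not tested, since the channel of the G-CSF DNA is unsettled.

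For the 15880 bins past the threshold, turning the sign of an array gives 4 sign patterns with the deposited one. Only 1 pattern, the deposited one, gave as many bins, and the highest number in the others was 0. With 4 patterns the share cannot fall below 0.25. Since bin means of the arrays correlated at 0.862 to 0.934, turning 1 array was bound to cancel shared shifts. The count of patterns therefore cannot decide whether the bins arose by chance.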
